A study of Homo sapiens with 10 samples.

How the data were processed

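Peripheral blood mononuclear cells (PBMCs) of 10 children with systemic lupus erythematosus (SLE) were profiled by droplet single-cell RNA sequencing, with 1 library per donor. All 10 samples form a single group, and no control samples are in the set. The labels give no treatment, batch or date that would divide the donors. According to the labels, 12000 cells were loaded per library with 6000 targeted, samples had a viability of at least 70%, and 100000 read pairs per cell were aimed at. The labels name 10x chemistry versions 3 and 3.1 without saying which library used which.

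The deposited matrices hold whole-number UMI counts per gene and barcode, with no normalization by the authors. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14 and counted with Cell Ranger 3.0.2 on GRCh38 (hg38). Per the file headers, the matrices came from Cell Ranger 6.0.0, and which version made the counts was left open. No removal of doublets or of free RNA is given in the sources used here, and no annotation of cell types was used. The 10 feature lists were identical, with 36601 genes. XIST, TSIX and the genes of chromosome Y (103 genes in all) were left out of every total, clustering and test. Counts of all 45 pairs of libraries differed far beyond sampling noise (chi-square per degree of freedom 37.6 to 470.4), so that no library was a copy of another.

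Barcodes with fewer than 300 detected genes (3198) or more than 15% mitochondrial UMIs (7529) were left out, 8222 in all, which left 44185 of 52407 barcodes. Doublet scores came from simulated doublets within each library, and the highest-scoring barcodes were removed at 0.8% of a library per 1000 of its barcodes (1929 barcodes). The remaining 42256 cells were analysed.

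Each UMI was assigned at random to a clustering set (70%) or a test set (30%) with seed 11, so that clusters were made from other UMIs than those tested. All cells were clustered on 2000 variable genes and 30 principal components, leaving out the interferon-stimulated gene list. Donors were aligned in principal component space (soft clustering with a diversity penalty of 2, 60 clusters, 10 iterations), and Leiden clusters were taken at resolution 1.5 from a shared-neighbour graph of 20 neighbours. A cluster took the name of the cell class with the highest mean z-score over markers fixed before the data were examined. It needed a score of at least 1.5, at least 100 cells, at least 3 detected markers and, except for platelets and erythroid cells, a median UMI count of at least 1/3 of its own library. No other class could have more markers among the 10 leading genes. Naive CD4 cells were clustered again on 1500 variable genes and 15 components (resolution 0.6, 20 alignment clusters), with interferon genes allowed. A subcluster took a name where its z-score was at least 0.8 and at least 3 of the markers were highest in it. The markers were fixed beforehand, while these thresholds and resolutions were set after seeing the clusters. Every class name means a resemblance to that cell type ("-like"), which is not repeated at each mention.

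Test UMIs were summed per donor and class wherever a donor had at least 20 cells in both classes compared. All 10 donors met this in all 7 comparisons. The sums were tested with edgeR's quasi-likelihood F-test with the donor as a block, TMM normalization and filterByExpr (minimum count 10), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The pairing comes from the design, since the summed libraries of a donor came from the same person and the same 10x library. Per-gene values are means and SDs over donors of CPM (counts scaled to the library size) of test UMIs of the genes that passed the filter, scaled by TMM. Fold changes are log2. Their standard error (SE) was taken as the absolute log2 fold change over the square root of the F statistic, and is not a spread over donors. Test UMIs per donor ranged from 735489 to 2511583 in naive CD4 cells, 153703 to 890559 in memory CD4 cells and 202101 to 569767 in regulatory T cells. In the naive subclusters they ranged from 46972 in the smallest to 715318 in the largest.

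Of 22 gene lists fixed before the data were examined, members that rose, fell or did not pass were counted, adjusted over all genes tested and adjusted over the list alone. Each list with at least 3 tested members was tested against the other genes with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The p-values given for lists are those with the estimated correlation unless stated. The lists hold interferon-stimulated genes, interferon-gamma and antigen presentation genes, naive, recent thymic emigrant, memory, regulatory, follicular or peripheral helper, T helper 1, T helper 2, T helper 17 and cytotoxic genes, and immediate early, TGF-beta and quiescence, heat shock and cell cycle genes. The remaining lists hold markers of monocytes, B cells, platelets, erythroid cells and CD8 T cells, mitochondrial transcripts and ribosomal protein genes. The ribosomal list was taken by symbol (RPL or RPS and a number) and so holds some ribosomal S6 kinases, such as RPS6KA5.

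Genes were named by a rule fixed before the data were examined. It took the 10 genes with the largest log2 fold change in each direction among those that passed, with a mean of at least 10 CPM and the same sign in at least 90% of donors. Mitochondrial, ribosomal, immunoglobulin and T cell receptor variable genes were left out of that part. From each list the rule added up to 4 members with the lowest adjusted p, or the most abundant member where none passed. Other members given with a value were chosen after their values were seen. Values of some genes that the rule names are not reported here. Positions came from GENCODE release 29 on GRCh38 for 221 of 221 named genes, matched by gene ID.

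The interferon level of a class was the mean of log2(CPM + 1) over the 44 interferon-stimulated genes, from all UMIs of a donor's cells of that class. Each of 13 classes was compared with naive CD4 cells by an exact two-sided sign-flip permutation test over donors (1024 flips with 10 donors). Levels were correlated across donors by Pearson's r and Spearman's rho with two-sided permutation tests (100000 resamples, or all permutations below 10 donors), and again without the 2 donors farthest from the median in naive CD4 cells. Both families were adjusted over the 13 classes.

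Alternatives chosen before the data were examined were a mitochondrial limit of 8%, no doublet removal, lower and higher resolution (1 and 2 for all cells, 0.4 and 1 for naive cells), no donor alignment, clustering on 50% of the UMIs and naive clustering without the interferon genes. For the gene tests they were RLE size factors, no count filter, DESeq2, no replicate block, all UMIs, and cells thinned to 1000 test UMIs. Thinning left out the shallower cells, 389 naive, 152 memory and 165 regulatory ones. For the interferon level they were pseudocounts of 0.1 and 10 CPM and the 37 list genes with at least 10 CPM in every class. TMM scaling over each class and naive CD4 cells, for the interferon level, was added after the results were seen. The main resolutions were set after seeing the clusters, and so were the values of the lower and higher ones around them. Each donor was also left out in turn. Clusters of an alternative took the name of the main cluster that held most of their cells.

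The scripts were tested on simulated data. For counts drawn from the real means with 200 changed genes, edgeR recovered 67% of 1.5-fold and 87% of 2-fold changes between memory and naive cells (5767 genes), and 61% and 90% between regulatory and memory cells (4171 genes). For the naive subclusters 1 to 5, it recovered 78%, 61%, 70%, 72% and 52% of 1.5-fold changes and 95%, 95%, 90%, 90% and 89% of 2-fold changes (4867, 4715, 4720, 4523 and 3631 genes). False calls made up 1.7% to 5.03% of the calls. When a simulated population without structure was split into 5 clusters, 0 to 1 of the 4319 to 4789 genes tested were called with held-out UMIs, against 13 to 51 of 8188 to 8569 with all UMIs. All simulated cells of a donor were drawn from the same profile, so that this does not cover gradual differences between real cells. Aligning simulated donors raised the adjusted Rand index from 0.139 to 1.

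Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.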

Results

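PBMCs of 10 children with SLE, an autoimmune disease with a strong type I interferon signature in blood, were measured by single-cell RNA sequencing. The set consists of 10 libraries from 10 donors in a single group without controls, and each comparison was therefore made between cell classes within donors. The series states that these libraries served to check subclusters of naive CD4 T cells, and its title names helper and regulatory CD4 clusters. The libraries held 3208 to 7117 barcodes (52407 in all) and 27981845 to 48469629 UMIs (363223054 in all). The median per barcode was 4396 to 7194 UMIs and 1457 to 2184 genes, and the median mitochondrial share was 3.24% to 5.41%.

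The 42256 analysed cells formed 32 clusters, of which 24 took the name of 1 of 16 cell classes, a name meaning a resemblance to that cell type. B cells made up 19.2% ± 14.3 (SD, n = 10) of the analysed cells and ranged from 2.5% to 49.9% between donors. Naive CD4 T cells, which express the chemokine receptor gene CCR7, made up 16.9% ± 6.69. CD14 monocytes accounted for 12.8% ± 4.74, naive CD8 T cells for 7.74% ± 3.21 and memory or effector CD8 T cells for 7.28% ± 3.09. Memory CD4 T cells made up 5.03% ± 2.39, regulatory T cells 4.81% ± 1.42, NK cells 4.6% ± 1.62 and CD16 monocytes 3.94% ± 2.87. Plasmablasts, the antibody-secreting cells of blood, reached 2.14% ± 2.49. Innate-like T cells made up 1.49% ± 1.28, cycling lymphocytes 1.20% ± 0.54, platelets 1.00% ± 0.64 and erythroid cells 0.657% ± 0.265. Plasmacytoid dendritic cells accounted for 0.309% ± 0.227 and conventional dendritic cells for 0.255% ± 0.313. Among CD4 T cells, 62.9% ± 9.28 were naive (46.4% to 74.3%), 18.7% ± 6.77 were memory cells (11.7% to 30.6%) and 18.4% ± 3.27 were regulatory (12% to 23%).

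The 8 clusters without a name held 10.7% ± 1.79 of the analysed cells (7.72% to 13.6%), with a median of 2041 UMIs and 7.25% mitochondrial UMIs, against 6241 UMIs and 3.05% in naive CD4 cells. They differed in depth. The largest, of 1431 cells, had a median of 1823 UMIs. Another, of 946 cells, had 6308 UMIs and 3.815% mitochondrial UMIs. Its best score, for naive CD8 T cells, was 1.342 and so below the minimum, and its cells are not in the shares of the named classes. The regulatory share of CD4 T cells depended on which cells were kept and on the clustering, and was 13.9% with the mitochondrial limit at 8%, 13.6% without doublet removal and 12.9% without donor alignment.

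**Figure D1:**
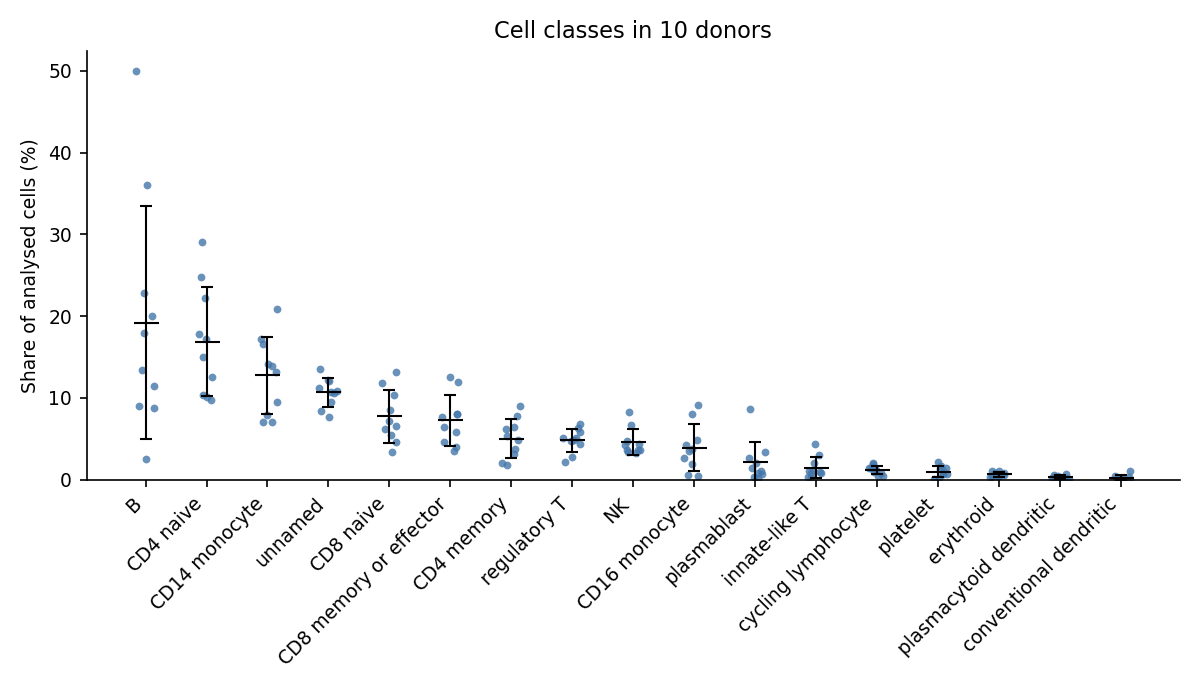
Share of each cell class among the analysed cells of a donor, in percent, with 1 dot per donor and a black bar for the mean and SD over 10 donors. B cells, at 19.2% ± 14.3, had the widest spread between donors.

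Memory CD4 T cells were compared with naive CD4 T cells to describe the helper programmes that the title of the series refers to. Relative to naive cells, memory cells expressed more of the memory, T helper 17 and immediate early genes, and less of the naive T cell genes. KLRB1 (ENSG00000111796, chromosome 12, 9594551 to 9607886 on GRCh38), which encodes the lectin receptor CD161, was at 336 ± 114 CPM in memory and 8.42 ± 5.51 CPM in naive cells (log2 fold change 5.39, SE 0.13, adjusted p = 9.88e-34, n = 10). It was higher in 10 of 10 donors. Conversely, LRRN3, a leucine-rich repeat gene of naive T cells, was 4.23 lower on the log2 scale (2.80 ± 2.10 against 51.5 ± 25.1 CPM). Of 6028 genes tested, 2204 differed, 1138 higher and 1066 lower in memory cells, of which 208 and 96 differed at least 2-fold.

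All 20 tested memory genes rose (adjusted p of the list 0.00225 with an estimated correlation). The calcium-binding protein gene S100A4 rose by 3.15 (SE 0.05), the integrin gene ITGB1 by 3.79 (SE 0.09) and the galectin genes LGALS1 and LGALS3 by 3.47 and 4.40. Among naive T cell genes, 13 of 16 fell, 2 rose and 1 did not pass (list adjusted p = 0.00244). CCR7 changed by −2.17 (SE 0.13), the transcription factor gene LEF1 by −1.50 (SE 0.08), and FHIT by −2.39 (SE 0.14). The members that rose were the costimulatory receptor gene CD28 (0.50) and KLF2 (0.30). Both tested recent thymic emigrant genes fell, with log2 fold changes of −3.52 (SOX4) and −1.13 (SATB1). The 10 genes with the largest falls also included LEF1-AS1, CHI3L2, SCML1, TTN, ANKRD55, ADTRP and CERS6, with log2 fold changes from −3.07 to −2.40.

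All 4 tested T helper 17 genes rose (list adjusted p = 0.00235), among them the transcription factor gene RORA (1.78, SE 0.09) and the cathepsin gene CTSH (3.28, SE 0.19). CCR6, a chemokine receptor gene of T helper 17 cells, had 208 test UMIs in memory and 2 in naive cells, a CPM ratio of 302.2 with an exact 95% counting interval of 82.6 to 2512. Both tested T helper 1 genes rose, the chemokine gene CCL5 by 3.72 (SE 0.18) and the granzyme gene GZMK by 4.41 (SE 0.27). Of the T helper 2 genes, GATA3 rose by 1.79 (SE 0.12) and IL4R fell by 0.36 (SE 0.12). Of 3 tested follicular or peripheral helper genes 2 rose, MAF by 4.30 (SE 0.16) and ICOS by 0.46 (SE 0.14), and the list did not pass (adjusted p = 0.137). Of 6 tested cytotoxic genes 5 rose, GNLY and GZMA among them, while GZMM changed by −0.56, and the call for the list (0.00967 with the preset correlation) was lost with an estimated one (adjusted p = 0.249).

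All 7 tested members of the regulatory T cell list rose (adjusted p = 0.00225), although FOXP3, the defining transcription factor gene of regulatory cells, was below the count filter here. TNFRSF4 (OX40) rose by 5.61 (SE 0.18), IL10RA by 2.05 and TNFRSF1B by 1.86, all of which encode receptors that activated T cells also carry. TNFRSF18 (GITR) had 218 test UMIs in memory and 2 in naive cells, a CPM ratio of 316.8 with an exact 95% counting interval of 86.6 to 2632. Of 18 immediate early and activation genes 17 rose (list adjusted p = 0.00235), among them KLF6 (1.89, SE 0.07), DUSP2 (1.91, SE 0.10), ZFP36 (1.46, SE 0.07) and DUSP1 (1.32, SE 0.08). NIBAN1, CYTOR, ADAM19 and MYO1F were the other genes among the 10 with the largest rises, with log2 fold changes from 4.62 to 5.49.

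Of 44 interferon-stimulated genes 24 rose and none fell, and the call with the preset correlation (2.71e-06) was lost with an estimated one (adjusted p = 0.0574). IFI27 rose by 2.87 (SE 0.14), OASL by 1.46 (SE 0.16), ISG15 by 0.63 (SE 0.06) and LY6E by 0.49 (SE 0.05). Interferon-gamma and antigen presentation genes rose in 13 of 19 cases (adjusted p = 0.0256), including TAP1 (0.79), B2M (0.45) and HLA-B (0.36). Of 88 tested members of the ribosomal list 78 fell and 3 rose, and the call (3.73e-21 with the preset correlation) was lost with an estimated one (adjusted p = 0.0619). RPL21, RPS3A, RPS13 and RPS23 changed by −0.66 to −0.58, and the members that rose were the kinase genes RPS6KA3 (0.92) and RPS6KA1 (0.61) and the gene RPL36AL (0.18). Members of 4 lists went both ways or mostly did not pass. For TGF-beta and quiescence genes, 4 of 11 rose (TGFB1 by 0.76, TOB1 by 0.83) and 3 fell (TGFBR2 at −1.142, FOXP1 at −0.71). For heat shock genes, 3 of 8 rose (HSP90AA1 by 0.55, DNAJB1 by 0.43, HSPA8 by 0.12) and HSPB1 fell by 0.85. For cell cycle genes, 2 of 6 fell (STMN1 by 1.98, MCM7 by 0.65), and for mitochondrial transcripts 2 of 13 rose (MT-CO1, MT-ND5) and 3 fell, MT-ND3 and MT-ND4 among them. None of these 4 lists passed (adjusted p from 0.578 to 0.908).

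Of the markers of other cells, the monocyte genes LYZ (54.1 ± 47.3 against 65.3 ± 52.9 CPM), FCN1 and S100A8 fell, by 0.29, 0.55 and 0.28, and CTSS, which T cells also express, rose by 0.21 (list adjusted p = 0.578). The B cell gene IGKC was at 183 ± 196 CPM in memory and 228 ± 253 CPM in naive cells, a fall of 0.31, while CD79B rose by 1.27 (list adjusted p = 0.871). No platelet, erythroid or CD8 T cell gene passed the count filter. The counts adjusted over the list alone were the same, except for 1 interferon-stimulated gene that fell, 16 interferon-gamma genes that rose, 4 ribosomal genes that rose and 4 mitochondrial transcripts that fell. CCR7, LEF1, FHIT, S100A4 and ITGB1 are among the genes that served to name the classes, so that their direction, read in held-out UMIs, was in part fixed by the naming. The count was 4546 with all UMIs and 1129 in thinned cells, where fewer genes (3456) passed the count filter.

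Regulatory T cells were compared with memory CD4 T cells, since the title of the series also names regulatory clusters. Regulatory cells had more of the regulatory T cell genes, and less of the immediate early and T helper 17 genes, than memory cells. Both comparisons share the memory cells, and regulatory cells were not tested against naive cells. The median log2 fold change of the immediate early list was 0.91 in memory against naive cells and −0.89 in regulatory against memory cells. FOXP3 (ENSG00000049768, chromosome X, 49250436 to 49264826) was at 70.5 ± 17.4 CPM in regulatory and 3.6 ± 3.4 CPM in memory cells (log2 fold change 4.07, SE 0.26, adjusted p = 1.16e-15, higher in 10 of 10 donors). IKZF2, which encodes the transcription factor Helios, rose by 4.22 (SE 0.24), and the inhibitory receptor genes TIGIT and CTLA4 by 3.17 (SE 0.15) and 2.25 (SE 0.22). IL7R, the interleukin-7 receptor gene, fell from 1985 ± 417 to 532 ± 155 CPM (log2 fold change −1.92, SE 0.07). Of 4359 genes tested, 913 differed, 390 higher and 523 lower in regulatory cells, of which 37 and 63 differed at least 2-fold.

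In the regulatory T cell list 8 of 12 tested members rose, 1 fell and 3 did not pass (adjusted p = 0.0323), with RTKN2 rising by 2.22 (SE 0.16) and TNFRSF4 changing by −0.47. FOXP3, CTLA4, TIGIT, RTKN2 and IKZF2 also served to name the class, and IL7R, LTB and GPR183 to name memory cells. ICA1, CPA5, MIR4435-2HG, CCDC50 and FABP5 completed the 10 largest rises, from 1.85 to 3.64. All 3 tested T helper 17 genes fell (list adjusted p = 0.0323), with CTSH at −2.23, KLRB1 at −1.49 and RORA at −0.41. Of the 2 T helper 1 genes tested CCL5 fell by 2.18 (lower in 9 of 10 donors). GZMK was at −0.90 but lower in only 6 donors and higher in 4, and at the lower resolution it was at 0.04 (SE 0.23, adjusted p = 0.942). Both T helper 2 genes fell, IL4R by 1.20 and GATA3 by 0.75. Of 7 cytotoxic genes 5 fell, GZMA by 1.03 and GZMM by 0.48 among them, while CST7 rose by 0.51, and the call (0.04999 with the preset correlation) was lost with an estimated one (adjusted p = 0.329).

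Immediate early and activation genes fell in 17 of 18 cases (adjusted p = 0.0345). TNFAIP3, an inhibitor of NF-kappaB signalling, was at −1.63 (SE 0.09), the AP-1 gene FOS at −1.52 (SE 0.10), CD69 at −1.22 (SE 0.08) and NFKBIA at −1.19 (SE 0.08). Memory genes fell in 13 of 22 cases, ANXA1 by 2.06, LTB by 1.20 and VIM by 0.63 among them, and their call (1.49e-05 with the preset correlation) was lost with an estimated one (adjusted p = 0.186). BHLHE40, DPP4, DUSP5, MYBL1, USP10 and ERN1 were the other genes among the 10 largest falls, from −2.97 to −1.78. Naive T cell genes went both ways, with 6 of 14 higher (LEF1 1.11 and CD27 1.05 among them) and 4 lower (NOSIP −0.78), and the list did not pass (adjusted p = 0.469). Of the recent thymic emigrant genes, SATB1 changed by −0.59 and IKZF2, counted above, rose.

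Interferon-gamma and antigen presentation genes rose in 9 of 19 cases, while IRF1 and HLA-B fell by 0.24 and 0.15, and the call (0.000383 with the preset correlation) was lost with an estimated one (adjusted p = 0.0942). The class II genes HLA-DRB1 and HLA-DPB1 rose by 1.54 (SE 0.20) and 1.136 (SE 0.13), and the guanylate-binding protein genes GBP5 and GBP2 by 0.91 and 0.74. Interferon-stimulated genes rose in 14 of 44 cases and none fell, with ISG15 at 1549 ± 934 CPM in regulatory and 1073 ± 591 CPM in memory cells (0.51, SE 0.07). IFI27 rose by 0.80, EPSTI1 by 0.60 and ISG20 by 0.33, and the call for the list (0.000308 with the preset correlation) was lost with an estimated one (adjusted p = 0.186). Ribosomal genes fell in 77 of 88 cases, RPLP0, RPL36A, RPL10 and RPL23A by 0.60 to 0.48, while RPS27L rose by 0.28 (adjusted p = 0.16 with an estimated correlation, 1.30e-25 with the preset one).

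Heat shock genes fell in 4 of 8 cases (HSP90AB1, DNAJB1, HSPE1 and HSP90AA1), and their call was lost with an estimated correlation (adjusted p = 0.16). In thinned cells HSPE1 was at 0.00. The cell cycle genes HMGB2 and STMN1 rose by 0.61 and 1.03 (2 of 4 tested, adjusted p = 0.362). Among TGF-beta and quiescence genes 2 of 10 rose, FOXO1 by 0.78 and SLFN5 by 0.28, and 4 fell, TOB1 by 1.41, BTG1 by 0.46, TGFB1 by 0.40 and KLF2 by 0.24 (adjusted p = 0.546). Among follicular and peripheral helper genes TIGIT rose and MAF fell by 0.38 (1 of 4 tested each), and the call was lost with an estimated correlation (adjusted p = 0.186). Of 13 mitochondrial transcripts MT-CO1 rose by 0.17, and MT-ND4L and MT-ND2 fell by 0.27 and 0.15 (adjusted p = 0.763). No monocyte or B cell gene passed, with CTSS at 145 ± 31.7 against 175 ± 33.8 CPM and IGKC at 210 ± 230 against 210 ± 227 CPM. No platelet, erythroid or CD8 T cell gene was tested. When adjusted over the list alone, 15 interferon-stimulated, 11 interferon-gamma, 7 naive and 2 follicular helper genes rose, and 18 immediate early, 80 ribosomal, 5 heat shock, 3 mitochondrial and 2 regulatory genes fell, with all other counts the same. DESeq2 called 572 genes, a fit without the donor block 469, a test on all UMIs 2140 and thinned cells 471 of 2202 tested.

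Naive CD4 T cells, the population the series set out to check, separated into 5 subclusters, each present in all 10 donors. This presence and the small SDs below were in part set by the donor alignment, which favours clusters that hold every donor. Without it, subclusters 2 to 5 held 26.5% ± 36.3, 26.2% ± 28.1, 32.8% ± 27.5 and 14.5% ± 17.1 of naive CD4 cells (SD over donors). Subcluster 1 (1833 cells, 24.9% ± 2.68 of naive CD4 cells, SD, n = 10) met the criteria for recent thymic emigrant-like cells, which have left the thymus lately. Subcluster 2 (1642 cells, 23.1% ± 2.39) met those for immediate early expression, with a marker z-score of 1.49, and its score for memory transition genes was 1.36. Subcluster 3 (1612 cells, 22.5% ± 1.83) and subcluster 4 (1324 cells, 19.0% ± 2.28) met none. Subcluster 5 (693 cells, 10.5% ± 3.89, 5.60% to 17.2% between donors) met those for interferon-high cells. The median was 5914, 6714.5, 5726.5, 6559.5 and 6673 UMIs per cell in subclusters 1 to 5. Each subcluster was tested against all other naive CD4 cells of the same donors, so that the cells compared with subclusters 1 to 4 include the interferon-high ones. Likewise, a rise in any subcluster can appear as a fall in the others. This applies to SOX4 (high in subcluster 1), immediate early genes (high in subcluster 2) and SOCS2, CISH and CDK6 (high in subcluster 4). Such falls are not separate traits of the other subclusters.

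The limits of the subclusters moved with the clustering. Only 37.3% to 67.2% of naive CD4 cells kept their subcluster under 7 other clusterings, while 93.3% to 99.3% of all cells kept their class under the 6 clusterings that redid the classes. Subcluster 1 was not found at the lower resolution or without donor alignment, subcluster 2 not with clustering on 50% of the UMIs, and subcluster 5 not when interferon genes were left out of the naive clustering. A fit without the donor block called no gene in subclusters 1 to 3. With the main settings, no T helper 1, platelet or CD8 T cell gene passed the count filter in any subcluster. The only tested erythroid gene was HBB in subcluster 3. CD8B was, however, among the leading genes of subcluster 3 in the clustering UMIs. Some alternatives tested CD8 T cell genes, with median log2 fold changes of 0.45 to 1.385 in subcluster 1 (3 settings). In subcluster 3 the medians were −0.508 to 0.782 (7 settings), and in the other subclusters they were negative. Without the count filter the share of calls that were higher fell to 3.27%, 13.1%, 19.1%, 16.4% and 23% in subclusters 1 to 5, from 28.6%, 45.3%, 65.3%, 52.1% and 91.8%, and the median log2 fold change over all genes moved to −0.12, −0.12, −0.20, −0.18 and −0.35.

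In subcluster 5, every tested interferon-stimulated gene rose (43 of 43, median log2 fold change 1.24, adjusted p = 0.0166), in a subcluster that was made with these genes in the clustering. IFIT3 (ENSG00000119917, chromosome 10, 89327894 to 89340971), an interferon-induced antiviral gene, was at 485 ± 334 CPM in subcluster 5 and 96.4 ± 98.3 CPM in the other naive cells (log2 fold change 2.47, SE 0.15, adjusted p = 4.06e-24, higher in 10 of 10 donors). The ubiquitin-like modifier ISG15 rose by 1.98 (SE 0.10), IFI6 by 1.84 (SE 0.10), MX1 by 1.64 (SE 0.10) and IFIT2 by 2.27 (SE 0.20). CMPK2, HERC5, RSAD2, IFIT1, PLSCR1 and USP18 were the other leading genes, with log2 fold changes from 1.70 to 2.18. Of 3799 genes tested, 158 differed, 145 higher and 13 lower, of which 50 and 1 differed at least 2-fold. Interferon-gamma and antigen presentation genes rose in 13 of 17 cases, GBP1 by 1.55, GBP4 by 1.37, PSMB9 by 0.64 and B2M by 0.14, but the call (1.74e-09 with the preset correlation) was lost with an estimated one (adjusted p = 0.121). Without the count filter B2M was at −0.07 (SE 0.03).

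Of 16 naive T cell genes 2 rose, CCR7 by 0.37 among them, and SLFN5 and the chaperone gene HSPA8 rose by 0.45 and 0.32. The falls were smaller, with GPCPD1, DNMT3A and ALG13 at −0.98 to −0.85, MBP at −0.55 and SOX4 at −0.52 (SE 0.16). AKAP9, LIME1 and FTL fell by 0.46, 0.33 and 0.23, and the memory genes S100A6 and VIM by 0.33 and 0.26. No immediate early, T helper, cytotoxic, regulatory, follicular helper, cell cycle, mitochondrial, monocyte or B cell gene passed. Among the most abundant of these, JUNB was at −0.05, CTSS at 0.29 (161 ± 60.4 against 127 ± 25.2 CPM) and IGKC at −0.13. No ribosomal gene passed (0 of 87, adjusted p = 0.767 with an estimated correlation, 0.00366 with the preset one), with RPS27 at 0.03, while without the count filter 77 of 98 fell and RPS27 was at −0.19 (SE 0.03), against the shift of −0.35 given above. With clustering on 50% of the UMIs 42 of 88 rose and 1 fell, and GPCPD1 was at 0.00. In counts adjusted over the list alone, 14 interferon-gamma genes and 1 monocyte gene rose and 1 naive and 1 monocyte gene fell, with all other counts the same. In thinned cells 37 of the 37 interferon-stimulated genes tested still rose.

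In subcluster 1, SOX4 (ENSG00000124766, chromosome 6, 21592768 to 21598619), a transcription factor gene expressed in thymocytes and recent thymic emigrants, was at 206 ± 124 CPM against 67.1 ± 51.8 CPM (log2 fold change 1.49, SE 0.09, adjusted p = 1.22e-28, higher in 10 of 10 donors). It was the only 1 of 3 tested recent thymic emigrant genes that passed (list adjusted p = 0.02), so that the name rests on it in the held-out UMIs. SOX4 is also among the markers that named the subcluster, so that its direction was in part fixed by the naming. Immediate early genes fell in 14 of 17 cases (adjusted p = 0.02), DUSP1 by 0.81, FOS by 0.75, JUNB by 0.72 and JUN by 0.69. Interferon-stimulated genes fell in 22 of 43 cases (adjusted p = 0.02), IFIT3 by 0.99, IFIT1 by 0.86, ISG15 by 0.68 and IFI6 by 0.54, relative to cells that include subcluster 5. Of 5053 genes tested, 371 differed, 106 higher and 265 lower, of which 1 and 2 differed at least 2-fold. With the mitochondrial limit at 8%, where the cluster of this name held 48.1% of the cells of subcluster 1, SOX4 was at 0.19 (SE 0.09, adjusted p = 0.17), and without the donor block at 1.59 (SE 0.41, adjusted p = 0.241).

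The other leading genes of subcluster 1 were LYST, NOL4L, NBPF19, ZNF141, ASAP1, GOLGA8B, MTHFD2L, SH2D1A and LINC00342, with rises from 0.53 to 0.85, but ASAP1 was at −0.14 with clustering on 50% of the UMIs and MTHFD2L at −0.04 with the mitochondrial limit at 8%, where IRF1 was at 0.06. NBPF19 and GOLGA8B belong to families of near-identical copies, so that their counts are uncertain. AL121944.1, LINC00513, TSHZ2, QDPR, HERC5, SOCS2 and AP3M2 led the falls, from −1.12 to −0.78. TCF7, CD28 and NOSIP rose (0.17, 0.42 and 0.14) and KLF2 and MAL fell by 0.19 each, and the call for the 16 naive genes (0.044 with the preset correlation) was lost with an estimated one (adjusted p = 0.0856). The memory genes GPR183, ANXA1 and S100A4 fell by 0.75, 0.60 and 0.29 (3 of 15, adjusted p = 0.708). Interferon-gamma genes fell in 6 of 18 cases (GBP5 by 0.70, GBP4 by 0.57, IRF1 by 0.36, B2M by 0.09) and ribosomal genes in 73 of 88 (RPLP1 by 0.22, RPL36 by 0.18, RPS12 and RPS14 by 0.17). The calls for both lists (0.00233 and 1.05e-13 with the preset correlation) were lost with an estimated one (adjusted p = 0.0856 for each). STMN1 (1 of 4 cell cycle genes) and SH2D1A (1 of 2 follicular helper genes) rose by 0.52 and 0.54, BTG1 and KLF2 (2 of 11 TGF-beta and quiescence genes) fell, and HSPA8 fell by 0.19 (1 of 8 heat shock genes, adjusted p = 0.0856). RORA (−0.14), IL4R (−0.25), GZMM (0.09), IL10RA (−0.15), CTSS (−0.23), IGKC (0.12) and MT-CO3 (0.01) did not pass, nor did any other member of their lists. Adjusted over the list alone, 29 interferon-stimulated, 9 interferon-gamma, 16 immediate early and 77 ribosomal genes fell and 2 recent thymic emigrant, 5 naive, 1 memory, 1 quiescence and 1 ribosomal gene rose. Over the list alone, 5 memory, 3 heat shock, 1 cell cycle and 1 monocyte gene also fell, and all other counts were the same.

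In subcluster 2, immediate early and activation genes rose in 15 of 18 cases (adjusted p = 0.0048). JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327), a component of AP-1, was at 1050 ± 485 against 692 ± 372 CPM (log2 fold change 0.61, SE 0.04, adjusted p = 4.04e-62, higher in 10 of 10 donors). JUNB and FOS each rose by 0.53 (SE 0.03 and 0.04), FOSB by 0.56 (SE 0.06) and IER5 by 0.68 (SE 0.15). JUN, JUNB, FOS and FOSB are among the markers that named this subcluster, and all of those markers are in the list. The direction of the list, read in held-out UMIs, was therefore in part fixed by the naming. GPR183, a chemotactic receptor gene of memory and follicular cells, rose by 0.78 (SE 0.12), the memory gene S100A4 by 0.33, while LTB and IL32 fell by 0.23 and 0.19 (3 higher and 2 lower of 15 memory genes, adjusted p = 0.775). SOX4, 1 of 3 recent thymic emigrant genes, and SOCS2, a target of cytokine signalling through STAT5, fell, with log2 fold changes of −1.37 (SE 0.11) and −1.33 (SE 0.21), and the recent thymic emigrant list passed (adjusted p = 0.04). Of 4902 genes tested, 150 differed, 68 higher and 82 lower, of which 0 and 3 differed at least 2-fold. At the lower resolution 2 of 17 immediate early genes rose, with JUNB at −0.08 and FOSB at −0.06, and SOX4 was at 0.13. With the mitochondrial limit at 8%, 7 of 17 rose and FOSB was at −0.01.

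TSHZ2, LIMS1, STX5, AL121944.1, OTULIN, TSPYL2 and ZNF331 were the other leading genes of subcluster 2, with rises from 0.59 to 0.77. CDK6, ADTRP, CISH, MAPKAPK3, SYNE3, FAM13A, CMPK2 and SLC50A1 led the falls, from −1.06 to −0.63. All of these except CMPK2 and SLC50A1, and SOCS2 as well, are leading rises of subcluster 4, which is among the cells compared. Interferon-stimulated genes fell in 11 of 43 cases (adjusted p = 0.00704), ISG15 by 0.37, IFI6 by 0.44, IFIT3 by 0.51 and ISG20 by 0.26, relative to cells that include subcluster 5. With naive clustering without interferon genes, where interferon-high cells no longer formed a subcluster, ISG15 was at 0.77 (SE 0.05) and IFIT3 at 0.89 (SE 0.09) in the cluster of this name. Ribosomal genes fell in 29 of 88 cases (RPS24 and RPL17 by 0.11, RPL13 and RPS27A by 0.09, adjusted p = 0.647, 0.00141 with the preset correlation). In the same clustering without interferon genes 43 of 88 rose, while at the lower resolution 79 of 88 fell. The former put RPL13 at 0.03, RPL17 at 0.00, RPS24 at 0.02 and RPS27A at 0.04. MT-CO3, MT-CYB and MT-ND3 fell by 0.08 to 0.10, MAL fell by 0.28, HLA-C fell by 0.08, and KLF2, BTG1 and TOB1 rose by 0.12, 0.11 and 0.32. At the lower resolution BTG1 was at −0.08 (SE 0.02, adjusted p = 0.0299), KLF2 at −0.04 and AL121944.1 at −0.05, and with the mitochondrial limit at 8% TOB1 was at −0.23, IL32 at 0.03 and ISG20 at 0.03. No heat shock, cell cycle, monocyte, B cell, T helper, cytotoxic or regulatory gene passed, with HSPA8 at 0.00, TUBA1B at −0.12, CTSS at 0.08, IGKC at −0.12, RORA at −0.06, IL4R at −0.30, GZMM at −0.26, IL10RA at 0.33 and ICOS at −0.04. Adjusted over the list alone, 21 interferon-stimulated, 43 ribosomal, 4 naive, 1 quiescence, 1 T helper 2 and 1 cytotoxic gene fell. Over the list alone, 16 immediate early, 4 memory, 4 quiescence, 3 naive, 2 ribosomal and 1 interferon-gamma gene rose, and all other counts were the same.

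In subcluster 3, ribosomal protein genes rose in 77 of 88 cases (median log2 fold change 0.20, adjusted p = 0.0134), by small amounts. RPL21 rose by 0.27 (SE 0.02), RPL13 by 0.23 (SE 0.01), and RPS27 and RPS12 by 0.22 (SE 0.01), each in 10 of 10 donors. Without the count filter, which moved the median of all genes to −0.20, 44 of 98 ribosomal genes rose with a median of 0.07. Of 13 mitochondrial transcripts 9 rose, MT-CO3 by 0.17 and MT-CO2 and MT-ATP6 by 0.15, and MT-ND6 fell by 0.27, but the call (0.00355 with the preset correlation) was lost with an estimated one (adjusted p = 0.435). None of them rose without the filter. Interferon-stimulated genes fell in 23 of 43 cases (adjusted p = 0.00654), RSAD2 by 0.94, IFIT3 by 0.74, MX1 by 0.46 and ISG15 by 0.35, relative to cells that include subcluster 5. Of 4853 genes tested, 340 differed, 222 higher and 118 lower, of which 1 and 0 differed at least 2-fold.

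That gene was HBB, the beta-globin gene of erythroid cells, at 1289 ± 2569 against 321 ± 761 CPM (log2 fold change 2.38, SE 0.14). It was higher in 5 donors and lower in 3, DESeq2 gave an adjusted p of 0.0566, and it fell below the count filter when any of 4 donors was left out. SOX4 led the clustering UMIs of subcluster 3 but was at 0.13 in the held-out ones (adjusted p = 0.489). ASB16-AS1, MAPK3, ADA, ERCC1, CYB5A, TUBB, CHI3L2, AC008105.3, FIBP and ECH1 rose by 0.37 to 0.89. Of these, 4 changed sign under an alternative, CYB5A with all UMIs (−0.02) and with clustering on 50% of the UMIs (−0.05), CHI3L2 without doublet removal (−0.03) and with 50% of the UMIs (−0.10), TUBB with 50% of the UMIs (−0.10) and ECH1 without donor alignment (−0.01), with no adjusted p below 0.05. Among the falls, FAM13A, LINC00342, TCOF1, GOLGB1, SEC14L1, TRAK2 and CALCOCO1 were at −0.83 to −0.73. B2M and HLA-C rose by 0.13 and 0.12 while GBP5 and GBP1 fell by 0.70 and 0.47 (2 and 2 of 18, adjusted p = 0.91). S100A6, IL32 and LTB rose by 0.20, 0.18 and 0.09 (3 of 15 memory genes, adjusted p = 0.0504, 0.0109 with the preset correlation), and KLF2, NOSIP, BTG1, GZMM and JUNB rose by 0.14, 0.18, 0.13, 0.35 and 0.10. Without the count filter BTG1 was at 0.00, HLA-C at −0.01, JUNB at −0.03 and LTB at −0.04. JUNB was also at −0.20 without donor alignment (SE 0.05, adjusted p = 0.00101) and LTB at −0.04 with 50% of the UMIs. CD28, SLFN5, HSP90AA1 and JUN fell by 0.52, 0.36, 0.23 and 0.14, but CD28 was at 0.03 at the higher resolution and 0.06 without donor alignment, and JUN at 0.00 without doublet removal. SATB1 (−0.04), TUBA1B (0.11), CTSS (−0.25), IGKC (0.03), RORA (0.14), IL4R (−0.15), IL10RA (−0.18) and ICOS (−0.05) did not pass, nor did any other member of their lists. Adjusted over the list alone, 30 interferon-stimulated, 3 quiescence, 2 immediate early, 1 memory and 1 monocyte gene fell, 7 memory, 4 naive and 3 interferon-gamma genes rose, and all other counts were the same.

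In subcluster 4, SOCS2, an inhibitor of cytokine signalling (ENSG00000120833, chromosome 12, 93569814 to 93583487) was at 84.6 ± 63.5 against 22.2 ± 15.6 CPM (log2 fold change 1.97, SE 0.15, adjusted p = 1.29e-26, higher in 10 of 10 donors). CISH, another inhibitor of cytokine signalling, rose by 1.26 (SE 0.12), the interleukin-4 receptor gene IL4R by 0.80 (SE 0.11) and the cell cycle kinase gene CDK6 by 1.56 (SE 0.11). FAM13A rose by 1.73 (SE 0.12) and ARID5B by 1.15 (SE 0.08), and STRADB, SYNE3, MAPKAPK3, DPP4 and ADTRP by 1.04 to 1.26. Of 4704 genes tested, 257 differed, 134 higher and 123 lower, of which 11 and 1 differed at least 2-fold. DESeq2 called 145 genes and a fit without the donor block 43.

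Among 16 naive T cell genes 2 rose and 6 fell (adjusted p = 0.789), with MAL at 0.56 (SE 0.06), TXK at 0.35, CD28 at −0.55, CD27 at −0.47 and TCF7 at −0.42 among them. SOX4 fell by 0.94 (SE 0.12), and APBB1, GLIPR2, NOL4L, SMC4, IKBKE, POU2F2, CCDC107 and SCML4 fell by 0.82 to 1.03. Interferon-stimulated genes fell in 16 of 42 cases relative to cells that include subcluster 5, IFIT3 by 0.70, ISG15 by 0.58, IFI6 by 0.43 and MX1 by 0.42, but the call (6.20e-10 with the preset correlation) was lost with an estimated one (adjusted p = 0.0776). GBP1 and B2M fell by 0.70 and 0.06 (2 of 17, adjusted p = 0.598), but B2M was at 0.01 to 0.02 in 3 of the other clusterings and IKBKE at 0.23 without donor alignment. LTB and CRIP1 rose by 0.30 and 0.28 and AQP3 fell by 0.51 (adjusted p = 0.789). HSP90AB1 rose by 0.27. In the ribosomal list the kinase gene RPS6KA5 and RPSA rose by 0.58 and 0.07 (2 of 88, adjusted p = 0.789), while without the count filter 74 of 98 fell and RPSA was at −0.06. Without donor alignment 67 of 88 fell, and with the mitochondrial limit at 8% 64 of 88 rose, so that the direction of this list depended on the setting. JUNB (0.01), BTG1 (−0.03), TUBA1B (0.04), MT-CO3 (−0.05), CTSS (0.23), IGKC (0.09), RORA (0.07), GZMM (−0.25), IL10RA (−0.06) and ICOS (0.27) did not pass, nor did any other member of their lists. Adjusted over the list alone, 25 interferon-stimulated, 2 memory, 1 follicular helper, 1 cytotoxic and 1 mitochondrial gene fell, 1 ribosomal and 1 monocyte gene rose, and all other counts were the same.

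**Figure D2:**
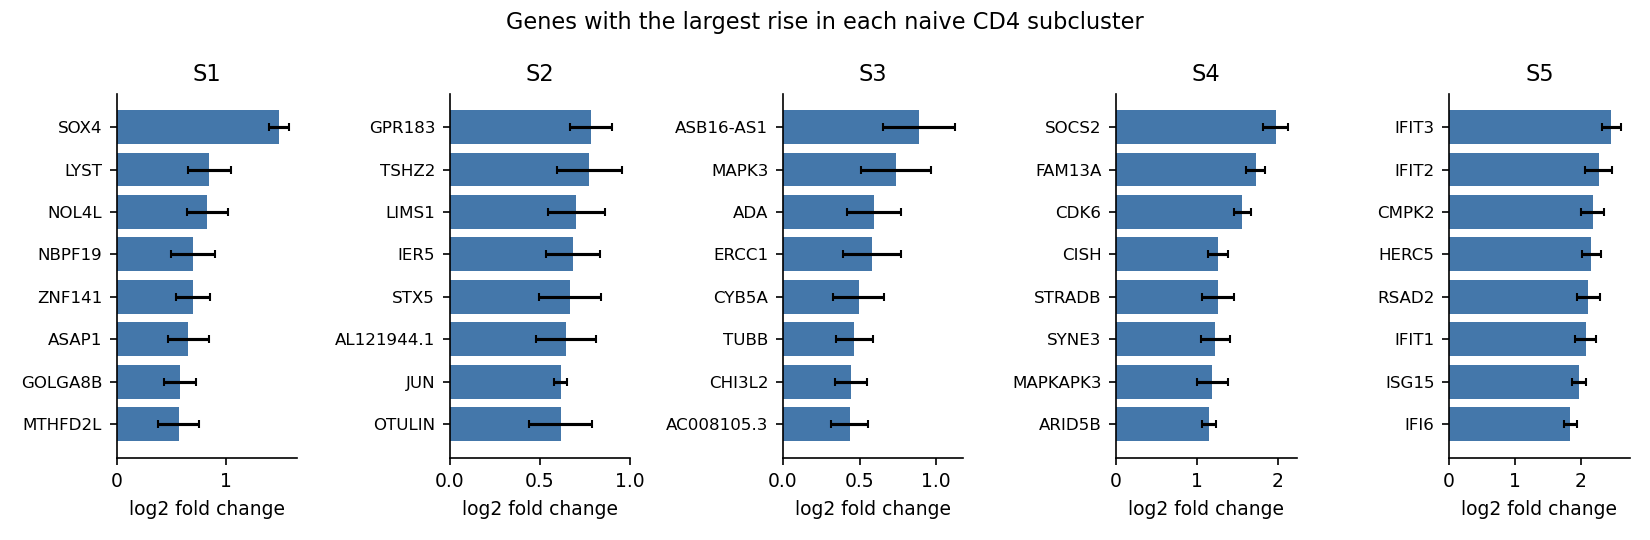
Log2 fold changes against all other naive CD4 cells, with SE, of the 8 genes with the largest rises in each naive CD4 subcluster by the naming rule, each panel with its own horizontal scale. The rises of subclusters 1, 4 and 5 reach 1.49 (SOX4), 1.97 (SOCS2) and 2.47 (IFIT3), and those of subclusters 2 and 3 stay below 1.

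The interferon level was compared between cell classes to show in which cells interferon-stimulated genes were highest. Over the 44 genes, the mean log2(CPM + 1) was 6.32 ± 0.73 (SD, n = 10) in naive CD4 cells and, among the 14 classes measured, highest in monocytes. Plasmacytoid and conventional dendritic cells were left out, since too few donors had at least 20 of them. CD16 monocytes were at 7.89 ± 0.58, which is 1.57 ± 0.22 above naive CD4 cells, and CD14 monocytes at 7.79 ± 0.53, or 1.47 ± 0.26 above. NK cells lay 0.95 ± 0.35 above naive CD4 cells, memory or effector CD8 cells 0.92 ± 0.32 and regulatory T cells 0.83 ± 0.27. Cycling lymphocytes lay 0.57 ± 0.35 above, memory CD4 cells 0.49 ± 0.11 and B cells 0.44 ± 0.12. Each of these 8 classes was higher in 10 of 10 donors (exact sign-flip permutation test, two-sided, p = 0.00195, the smallest possible, adjusted p = 0.00317). Innate-like T cells lay 0.73 ± 0.33 above, in 9 of 9 donors (exact sign-flip permutation test, p = 0.00391, adjusted p = 0.00564).

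The sizes of these differences depended on the scaling. With TMM over each class and naive CD4 cells, chosen after the results were seen, CD16 monocytes lay 1.33 ± 0.21 above naive CD4 cells, CD14 monocytes 1.32 ± 0.23, regulatory T cells 0.57 ± 0.24, memory or effector CD8 cells 0.55 ± 0.32, NK cells 0.48 ± 0.32, memory CD4 cells 0.38 ± 0.12 and B cells 0.34 ± 0.14 (10 of 10 donors each, exact sign-flip permutation test, adjusted p = 0.00363). Innate-like T cells lay 0.43 ± 0.28 above, in 8 of 9 donors (exact sign-flip permutation test, adjusted p = 0.0127). The call for cycling lymphocytes was lost (0.17 ± 0.38, higher in 6 of 10 donors, adjusted p = 0.227). In the gene test of memory against naive cells, on held-out UMIs and with TMM, the mean log2 fold change of the list was 0.32 and the median 0.22.

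Naive CD8 cells differed little from naive CD4 cells (−0.09 ± 0.11, lower in 7 of 10 donors, p = 0.0273, adjusted p = 0.0323). Leaving out any of 6 donors took this difference past the threshold (adjusted p = 0.0592 to 0.0646), as did TMM scaling (−0.07 ± 0.10, lower in 6 of 10 donors, adjusted p = 0.0705). Plasmablasts were lower by 0.49 on the log2 scale (SD 0.33, 7 of 8 donors, exact sign-flip permutation test, p = 0.0156, adjusted p = 0.0203). Immunoglobulin genes took 29.4% ± 4.08 of their UMIs, against 1.96% ± 0.41 in B cells and 0.05% ± 0.05 in naive CD4 cells. Their difference was −0.28 with a pseudocount of 10 CPM (adjusted p = 0.0646) and −0.19 over the list genes with at least 10 CPM in every class (adjusted p = 0.186). With TMM scaling it was −0.14 ± 0.31, lower in 6 of 8 donors (adjusted p = 0.227). Platelets (−0.96 ± 1.06, 7 donors, exact permutation test, adjusted p = 0.0508) and erythroid cells (−0.30 ± 0.99, 7 donors, exact permutation test, adjusted p = 0.469) did not pass. The median was 923 UMIs per cell in platelets and 857 in erythroid cells, against 6241 in naive CD4 cells. The levels of both classes therefore rest on few UMIs. For platelets the difference was −1.43 with a pseudocount of 0.1 CPM and −1.19 without 1 donor (exact permutation test, adjusted p = 0.0339 for both). For erythroid cells the difference ranged from −0.45 to −0.02 when each donor was left out in turn.

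**Figure D3:**
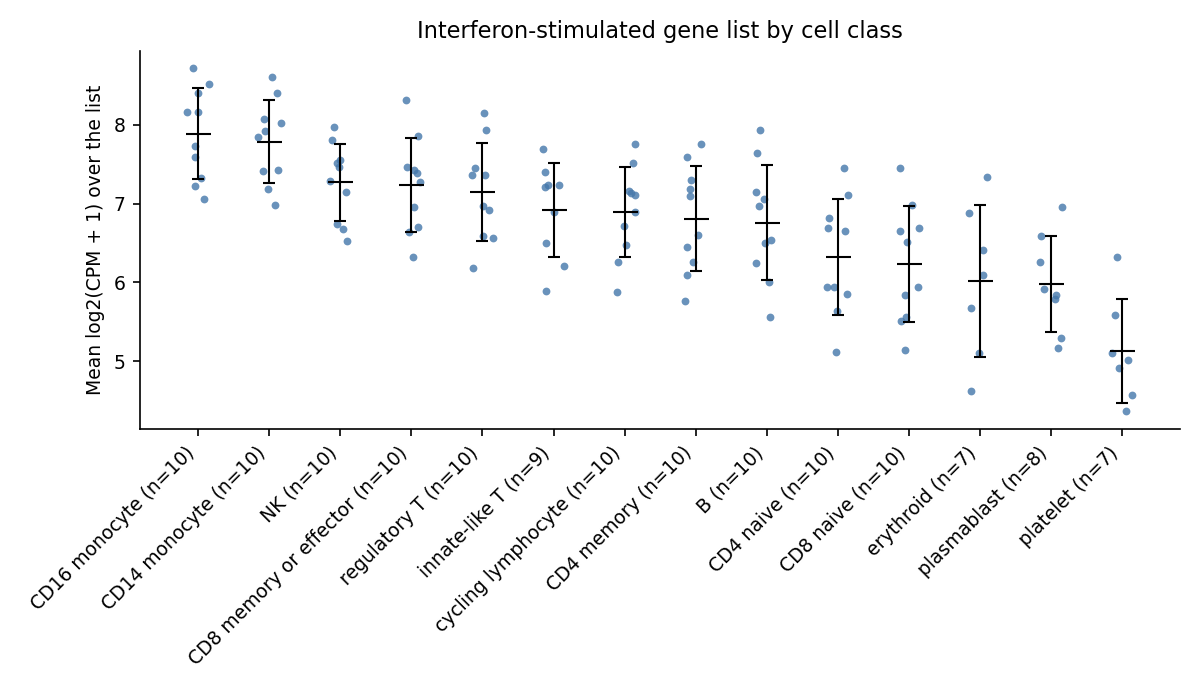
Mean log2(CPM + 1) over 44 interferon-stimulated genes in each cell class, with 1 dot per donor and a black bar for the mean and SD over donors. Among the classes shown, monocytes were highest, at 7.89 ± 0.58 (CD16) and 7.79 ± 0.53 (CD14), against 6.32 ± 0.73 in naive CD4 cells.

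Donors ranked alike in most classes. Across donors, the interferon level of naive CD4 cells followed that of memory CD4 cells (Pearson's r = 0.991, permutation p = 1e-05, the smallest the resamples can give, adjusted p = 6.5e-05, Spearman's rho = 0.988, p = 1e-05, n = 10). It also followed that of CD14 monocytes, a cell type of another lineage (r = 0.966, permutation p = 2e-05, adjusted p = 6.5e-05, rho = 0.952, p = 0.00013, n = 10). The r was 0.989 for naive CD8 cells, 0.986 for B cells, 0.971 for CD16 monocytes, 0.931 for regulatory T cells, 0.916 for NK cells, 0.906 for memory or effector CD8 cells and 0.882 for cycling lymphocytes, with rho from 0.915 to 0.964. Over these 9 classes the adjusted permutation p was at most 0.0013 for r and 0.00078 for rho. Plasmablasts (r = 0.907, rho = 0.929, exact permutation p = 0.00144 and 0.00223, adjusted p = 0.00187 and 0.00264, n = 8) and innate-like T cells (r = 0.867, rho = 0.933, exact permutation p = 0.00188 and 0.00075, adjusted p = 0.00222 and 0.000974, n = 9) gave similar values.

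Without the 2 donors farthest from the median, r was 0.9 to 0.988 over the 9 classes with 10 donors (exact permutation test, adjusted p from 0.00133 to 0.00208). It was 0.811 in plasmablasts and 0.814 in innate-like T cells (exact permutation test, adjusted p = 0.0476 and 0.0325). Platelets (r = −0.10, rho = 0.0714, exact permutation p = 0.828 and 0.906, n = 7) and erythroid cells (r = 0.321, rho = 0.357, exact permutation p = 0.483 and 0.444, n = 7) showed no relation that passed. The low depth of both classes, given above, limits these results. For platelets r was 0.808 without doublet removal (adjusted p = 0.00642), and for erythroid cells it ranged from 0.173 to 0.675 when each donor was left out in turn. With TMM scaling r was 0.809 to 0.988 over the 9 classes with 10 donors, and no correlation gained or lost its call. Free RNA of a library, which reaches all of its classes, was not removed from these levels. The labels divide the donors into no batches, so that no values within batches could be given.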

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

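The tests of the S5, S1 and S3 patterns (monocyte RNA, depth, naive CD8 cells, erythroid RNA) were chosen only after the results were seen. For these patterns no biological explanation was tested, since the design has a single group.

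The share of conventional dendritic cells was far from the others in 1 donor, at 1.05% of the analysed cells, with the next highest at 0.421%. The plasmablast share was far from the others in 1 donor, at 8.62%, with the next highest at 3.40%. The interferon level of B cells minus naive CD4 cells was lowest by a gap in 1 donor, at 0.154, with the next at 0.367. That of regulatory T cells minus naive CD4 cells was highest by a gap in 1 donor, at 1.48, with the next at 1.03. These are 4 of 56 groups of values examined, and chance marks about 1 in 20 groups.

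All 43 tested interferon-stimulated genes were high in naive CD4 subcluster 5. RNA from monocytes in the same droplets would need a median of 77.1% of monocyte RNA, while LYZ, S100A8 and S100A9 showed −0.069% ± 0.054 (SD over 10 donors), and 5 of the 43 members were not higher in monocytes. The marker values argue against monocyte RNA as the whole cause. A greater depth of these cells was predicted to end the rise in cells thinned to 1 depth. There 37 of the 43 still rose and the other 6 were not tested. The test cannot decide on depth, since thinning after the clustering keeps the expected make-up of each cell. What stays open is which genes besides these hold the subcluster together, since no subcluster 5 was found with the interferon genes left out of the clustering.

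SOX4 was high in subcluster 1. Naive CD8 T cells mixed into the subcluster would have to hold more SOX4 than it, but their mean was 31.38 ± 24.26 CPM against 196.44 ± 112.3 CPM in subcluster 1 (over all genes, without TMM scaling), lower in 10 of 10 donors. CD8A, CD8B and LINC02446 together showed 2.04% ± 5.04 of naive CD8 RNA. This argues against naive CD8 cells. The dependence of SOX4 on the limits of the subcluster stays open, with 0.185 for SOX4 under the mitochondrial limit of 8%.

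Ribosomal protein genes were high in subcluster 3. A lower depth of these cells was predicted to end the rise in thinned cells, where 76 of the 77 genes still rose. Thinning after the clustering keeps the expected make-up of each cell, so that this cannot decide on depth. Free RNA of erythroid cells would need a larger ribosomal part in those cells, but it was 15.91% ± 12.42 of their UMIs against 40.63% ± 2.81 in naive CD4 cells, lower in 9 of 10 donors, and HBB was higher in subcluster 3 in 5 of 10. These values argue against free RNA of erythroid cells. The size of the rise against the scaling of the libraries stays open, since without the count filter 44 of 98 rose. Naive CD8 T cells mixed into subcluster 3 were not tested, although CD8B was among its leading genes in the clustering UMIs.

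For the gene counts, other splits swapped the 2 summed libraries in a random set of donors (100 of 512 possible splits, the real one included). In each of the 7 comparisons 1 of 100 splits, the real one, called as many genes. This argues against chance as the source of the calls in the held-out UMIs. The classes were drawn over all donors together from other UMIs of the same cells. The splits therefore do not bear on where the limits were drawn, nor on whether a subcluster is a separate group of cells. The real count and the highest other were 2204 and 1395 for memory against naive cells, and 913 and 455 for regulatory against memory cells. For subclusters 1 to 5 they were 371 and 182, 150 and 62, 340 and 193, 257 and 123, and 158 and 142. The highest other split had 1 donor swapped in each case.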

How the results depend on the processing

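Among the alternatives, the TMM scaling of the interferon level was chosen after the results were seen, and the values of the lower and higher resolutions after the clusters were seen. Of 155 counts of called genes under alternatives 117 stayed within 1.5 times the main count, and of 149 shares 122 stayed within 1 SD. A change of sign was counted only where the main or the alternative value was called. By this rule, of 258 class differences in the interferon level 245 kept their direction and side of the threshold, 11 lost the call and 2 gained it, and of 258 correlations 257 did. Uncalled values also changed sign, such as the platelet correlation, which ranged from −0.235 to 0.339 when each donor was left out in turn. By the same rule, of 8178 values of named genes 7093 kept both, 969 lost the call, 57 gained it and 59 changed sign. Subcluster 1 had no counterpart at the lower resolution or without alignment, subcluster 2 none with 50% of the UMIs and subcluster 5 none without the interferon genes, so that these gave no values. Depth limits the smallest subcluster most, with 3799 genes tested in subcluster 5 against 6028 between memory and naive cells. The cause of the changes below was not tested, except that all UMIs let more genes pass the count filter and thinned cells fewer.

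The donor block comes from the design, since the summed libraries of a donor share a person and a 10x library. Without the replicate block edgeR called 469 genes between regulatory and memory cells, and 0, 0, 0, 43 and 81 in subclusters 1 to 5. For the counts of 0, 393, 181 and 438 genes had an unadjusted p below 0.05, and DESeq2 with the block called 205, 83 and 244.

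DESeq2 called 572 genes between regulatory and memory cells, 205 in subcluster 1, 83 in subcluster 2 and 145 in subcluster 4. With all UMIs the counts were 4546 (memory against naive), 2140 (regulatory against memory), and 1226, 539, 1163, 768 and 338 in subclusters 1 to 5. In thinned cells they were 1129, 471, 194, 72, 226, 124 and 91 in the same order. Without the count filter they were 259, 495 and 418 in subclusters 2, 4 and 5.

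With the mitochondrial limit at 8%, regulatory T cells were 13.9% of CD4 cells, unnamed cells 5.72% of analysed cells, and subclusters 2 and 3 8.95% and 34.4% of naive cells, with 609 genes called in subcluster 1 and 576 in subcluster 3. Without doublet removal, regulatory T cells were 13.6% of CD4 cells, plasmacytoid dendritic cells 0.668% of analysed cells, and subclusters 1 and 2 36.1% and 14.2%, with 580 genes in subcluster 1, and the platelet correlation was 0.808. At the lower resolution cycling lymphocytes were 0.381% and subclusters 2, 3 and 4 34.0%, 34.8% and 21.8%, with 398 and 585 genes in subclusters 2 and 3. At the higher resolution subclusters 2 and 3 were 17.5% and 29.8%. Without donor alignment regulatory T cells were 12.9% of CD4 and 3.32% of analysed cells, and subclusters 2 to 5 26.5% ± 36.3, 26.2% ± 28.1, 32.8% ± 27.5 and 14.5% ± 17.1 (SD over donors), with 52 genes in subcluster 2. There the subclusters differed widely between donors, only 8 or 9 donors could be tested, and the shares are not comparable with the main ones. With 50% of the UMIs regulatory T cells were 14.5% of CD4 cells, erythroid cells 1.04%, and subclusters 1 and 3 40.1% and 29.2%, with 646, 553 and 293 genes in subclusters 1, 3 and 5. With naive clustering without interferon genes subclusters 1, 2 and 4 were 35.5%, 26.3% and 16%, with 592 and 227 genes in subclusters 1 and 2.

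For the interferon level, platelets differed by −1.43 with a pseudocount of 0.1 CPM, and plasmablasts by −0.28 with 10 CPM and by −0.187 over list genes with 10 CPM in every class. With TMM scaling naive CD8 cells differed by −0.071, cycling lymphocytes by 0.168 and plasmablasts by −0.139, and all 3 lost the call. Leaving out each donor in turn gave −0.106 to −0.069 for naive CD8 cells, −1.19 to −0.644 for platelets, −0.449 to −0.021 for erythroid cells and −0.566 to −0.429 for plasmablasts. The gene counts then ranged over 1914 to 2181, 754 to 883, 289 to 361, 121 to 158, 280 to 359, 209 to 269 and 131 to 170, in the order given above.

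The named genes that changed sign by the rule above had these log2 fold changes. Regulatory against memory cells had HSPE1 0.004 in thinned cells and GZMK 0.038 at the lower resolution. At the lower resolution subcluster 2 had SOX4 0.128, FOSB −0.064, KLF2 −0.044, BTG1 −0.076, JUNB −0.078 and AL121944.1 −0.045, and at the higher resolution subcluster 3 had CD28 0.031. Without the count filter subcluster 1 had MT-CO3 −0.108, subcluster 3 BTG1 −0.002, JUNB −0.026, HLA-C −0.006 and LTB −0.039, subcluster 4 RPSA −0.055 and JUNB −0.126, and subcluster 5 B2M −0.075 and RPS27 −0.186. With the mitochondrial limit at 8% subcluster 1 had IRF1 0.061, MTHFD2L −0.036 and MT-CO3 −0.104, subcluster 2 IL32 0.033, FOSB −0.007, TOB1 −0.229 and ISG20 0.030, and subcluster 4 B2M 0.008. With 50% of the UMIs subcluster 1 had ASAP1 −0.139 and MT-CO3 −0.051, subcluster 3 CHI3L2 −0.095, CYB5A −0.049, TUBB −0.098 and LTB −0.038, subcluster 4 B2M 0.020 and subcluster 5 GPCPD1 0.003. With naive clustering without interferon genes subcluster 1 had MT-CO3 −0.080, subcluster 3 JUNB −0.056 and subcluster 4 B2M 0.007. There subcluster 2 had HSPA8 0.189, IFIT3 0.890, IFI6 0.515, CMPK2 0.817, ISG20 0.326, ISG15 0.768, RPS24 0.022, RPS27A 0.045, RPL13 0.033, RPL17 0.003, MT-CO3 0.020 and HLA-C 0.022. Without donor alignment subcluster 2 had RPL13 0.008, subcluster 3 ECH1 −0.009, JUNB −0.204 and CD28 0.059, and subcluster 4 RPSA −0.069, JUNB −0.217 and IKBKE 0.228. With all UMIs subcluster 3 had CYB5A −0.022, and without doublet removal CHI3L2 −0.027 and JUN 0.001.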

Other observations

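The tests of both hypotheses were written before their results were seen, and those of free RNA after. One hypothesis was that the donor-wide interferon level sets the share of naive CD4 cells in subcluster 5. Over 10 donors the share rose with the interferon level of CD14 monocytes (Pearson's r = 0.889, permutation p = 0.00093, Spearman's rho = 0.939, p = 0.00026). Without the 2 donors farthest from the median in monocytes, r was 0.879 (exact permutation p = 0.00392). This is consistent with the hypothesis, but a correlation over donors of a single group does not tell which comes first, the subcluster was made with the interferon genes, and free RNA was not removed from the counts.

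A second hypothesis was that only the cells of subcluster 5 carry the difference between donors in the interferon level of naive CD4 cells. Without these cells the level of naive CD4 cells still followed that of CD14 monocytes (r = 0.959, permutation p = 2e-05, rho = 0.952, p = 0.00017, n = 10). Without the 2 farthest donors r was 0.913 (exact permutation p = 0.00233). Free RNA of the same library was examined as a source of this relation. The values argue against free RNA of monocytes, since LYZ, S100A8 and S100A9 showed 0.42% ± 0.205 (SD over 10 donors) of the monocyte profile, and after its subtraction r was 0.96 (permutation p = 2e-05). Free RNA of all cells of the library would bring the markers of each cell type. Monocyte and B cell markers allowed 1.95% ± 0.71 and 1.71% ± 0.43 (SD over 10 donors) of the profile of all analysed cells, and platelet markers 10.4% ± 19.9. The largest part of the library profile that marker genes of monocytes, B cells, platelets or erythroid cells allowed was 59.8% ± 74 and came from globin genes in 7 of 10 donors, so that this limit is loose. Its subtraction left r at 0.516 (permutation p = 0.126), but this part is far above what the monocyte and B cell markers allowed, so that this r decides nothing. If free RNA had the profile of all analysed cells, the monocyte and B cell markers would limit it to the small parts given above. The subtraction of these small parts was not run, so that free RNA of this profile stays open as a source of the relation. With the limits of subcluster 5 drawn here, the level outside it thus still followed that of CD14 monocytes. Whether only its cells carry the difference cannot be decided from this. The limit on free RNA of the library is loose, and the subcluster was drawn after a donor alignment that favours clusters holding every donor. Free RNA of another make-up than the analysed cells was not tested.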
